A study of Coturnix japonica with 16 samples.

How the data were processed

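RNA was sequenced from the left liver lobe of 16 Japanese quail (Coturnix japonica) aged 12 weeks. Each bird had received, after a fast of 16 hours, 1 oral dose of 4 mL/kg into the crop. The dose held either corn oil alone or ethinylestradiol, a synthetic estrogen, in corn oil. Birds were kept on 8 hours of light and 16 hours of dark. Per the labels' protocols, RNA came from a silica column kit with a DNase step, and libraries followed a standard Illumina preparation. The interval between dosing and sampling, the sex of the birds and the strandedness of the libraries are not given in the sources used here.

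The deposited values are estimated counts per transcript from kallisto, per the submitters' processing notes. Its version (listed there as not given), the transcriptome release and the genome build are not given in the sources used here. The deposited table held 47418 transcript rows, each with an NCBI gene number. Estimated counts were summed over the transcripts of a gene, giving 20308 genes, and were then rounded to whole numbers, which changed a gene's count by at most 0.5. The largest values carry 3 significant digits. Kallisto shares out reads that match several transcripts, so counts of near-identical genes, of genes that overlap, and of neighbours whose transcripts run into each other are uncertain. Each of the 16 columns matched 1 sample by its name.

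Gene names and chromosomes came from the NCBI gene table of the assembly Coturnix japonica 2.1, matched by gene number, and 18900 of the 20308 genes matched. Since the build behind the counts is not known, no coordinates are given, and the assembly was used only for names, chromosomes and the order of neighbouring genes. Genes without a symbol there are called by their LOC identifier. The vitellogenins VTG1, VTG2 and VTG3, and APOV1, CYP7A1 and TTR, were not analysed here by name, because no gene in the name table carries those symbols.

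Total counts ran from 15172994 to 46192717 per library. Counts were analysed with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Genes were kept by filterByExpr with its defaults, a minimum count of 10 and a minimum total of 15, which left 13748 genes, of which 2869 carried a LOC identifier or no name. Libraries were scaled by TMM. A quasi-likelihood model with the 3 groups was fitted to all 16 libraries, so that the comparisons shared the spread between birds, with 13 residual degrees of freedom. The common dispersion was 0.126, a biological coefficient of variation of 35.4%. P-values were adjusted over all genes of a comparison by the Benjamini-Hochberg method, with a threshold of 0.05. Levels are given as counts-per-million values (CPM), mean ± SD, and per-library log2 CPM values used a prior count of 2. Adjusted p-values of genes come from edgeR's quasi-likelihood test unless another tool is named. The labels speak of separately dosed birds, and the p-values measure only the spread between these birds.

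The design, the alternatives, the gene lists and the rule for naming genes were fixed before the data were examined. The rule took APOB, ESR1, ESR2, PGR and the genes not analysed here by name. Among named genes past the threshold with a mean of at least 1 CPM in a group and every dosed library on the same side of the comparison mean, it took the 8 with the largest rise and the 8 with the largest fall. It also took up to 4 members of each list past the threshold, and, where fewer than 10 genes passed, the 5 with the lowest p. LOC107305801 was added after its values were seen, as a gene past the threshold. Members quoted for a list are those with the lowest p and were also chosen after their values were seen. Results of some genes are not reported here.

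Gene lists were tested with camera at its preset inter-gene correlation of 0.01, on lists with at least 5 genes tested, and p-values were adjusted over the 27 lists of a comparison. The lists covered yolk precursors and estrogen-induced genes, nuclear receptors, fatty acid synthesis, cholesterol synthesis, fatty acid oxidation, bile acids, lipoproteins, xenobiotic, steroid and thyroid hormone metabolism, the secretory pathway, the acute phase, interferon and cytokine signalling, the cell cycle, ribosome biogenesis, gluconeogenesis and growth factors, oxidative stress, iron and calcium, and the circadian clock. Markers of erythroid cells, macrophages, lymphocytes, endothelium, stellate cells, cholangiocytes, adipocytes and hepatocytes were included. The lists for exocrine pancreas (0 genes tested), skeletal and heart muscle (3 genes) and W-linked genes (0 genes) were too short to test. The yolk list had 34 genes, of which 16 were in the name table and 13 were tested. The cell type lists were tested in whole liver, where their genes may also be expressed by hepatocytes. The score of a list in a library is the mean of its genes' log2 CPM after centring each gene over all libraries.

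Replicates were compared before they were averaged. Correlations of log2 CPM lay between 0.928 and 0.968 within groups and between 0.914 and 0.967 across groups, no 2 libraries were identical, and the lowest chi-square per degree of freedom within a group was 50.7. Library numbers in the labels match the replicate numbers except at 5 mg/kg, where replicates 4 and 5 carry the numbers 5 and 6.

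The gene test was tested on simulated data with the real means, depths and spread among 13748 genes. For each comparison, 100 genes were changed by 2-fold and 100 by 4-fold. For 5 mg/kg against solvent 38% of the 2-fold and 87% of the 4-fold changes were called, with 10 false calls. The shares were 49% and 85%, with 16 false calls, for 0.5 mg/kg against solvent, and 41% and 80%, with 4 false calls, for 5 against 0.5 mg/kg. As a share of all calls, false ones exceeded 0.05 in both comparisons with solvent but not in 5 against 0.5 mg/kg. A single simulation was run per comparison, with each gene drawn on its own.

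Alternatives were DESeq2 size factors, no filter, a mean of at least 1 CPM, robust dispersions, only the 2 groups compared, a replicate block, a Z-linked expression covariate, 1 surrogate variable from sva 3.50.0, a log2 fold change of at least 1, limma-voom, the DESeq2 1.42.0 Wald test and leaving out each library. For lists, an estimated correlation and fry were also tried, on all libraries only. List values within a class of numbers or without a library therefore rest on the preset correlation. Where genes of a list vary together between birds, such values can be too low. Added after the data were seen were leaving out the 3 libraries farthest from the rest (solvent replicate 1 and 5 mg/kg replicates 1 and 5), using only replicates 1 to 3 or only 4 to 6, a covariate for these 2 classes of numbers, and a replicate block by the number in brackets in the labels. Each comparison was refitted on 100 splits of its libraries, the real one included. Files were read with version 1.17.8 of the data.table package.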

Results

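Liver RNA was measured in 6 quail given corn oil solvent, 5 given ethinylestradiol at 0.5 mg/kg and 5 given 5 mg/kg. Ethinylestradiol is the estrogen of many contraceptive pills and binds the estrogen receptors, which in the liver of egg-laying vertebrates switch on yolk precursor genes. Library totals were 24020961 to 38156083 counts for solvent birds, 15172994 to 30106081 counts at 0.5 mg/kg and 15825748 to 46192717 counts at 5 mg/kg. Mitochondrial transcripts took 12.0 ± 2.0% of counts in solvent birds (SD, n = 6), 10.3 ± 1.33% at 0.5 mg/kg (n = 5) and 10.8 ± 2.91% at 5 mg/kg (n = 5). Albumin, the main plasma protein made by hepatocytes, took 9.86 ± 1.88%, 10.7 ± 1.97% and 10.2 ± 1.37%. The first 2 principal components held 15.8% and 11.5% of the variance, and solvent replicate 1 lay farthest out on the first, at -85.5.

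Genes on the Z chromosome, of which male birds carry 2 copies and females 1, split the libraries by their replicate number. Over 401 expressed Z-linked genes, the median deviation from the gene means lay between 0.12 and 0.27 on the log2 scale in the 9 libraries numbered 1 to 3 and between -0.39 and -0.17 in the 7 numbered 4 to 6. Each dose group held both kinds, 3 and 3 libraries for solvent and 3 and 2 at either dose, so values within each class of numbers are given beside the pooled ones.

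**Figure D1:**
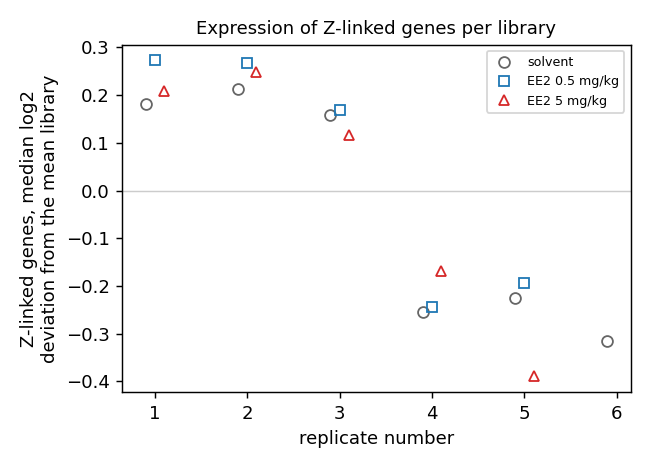
Median log2 deviation of 401 Z-linked genes from their means over all libraries (vertical axis) against replicate number (horizontal axis); each point is a library, with grey circles for solvent, blue squares for 0.5 mg/kg and red triangles for 5 mg/kg. Replicates 1 to 3 lie between 0.12 and 0.27 and replicates 4 and above between -0.39 and -0.17.

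The comparison of 5 mg/kg with solvent asked what a high oral dose of the estrogen did to liver transcripts. 6 genes rose and 0 fell. BBS2, a subunit of the complex that carries membrane proteins to cilia, rose most, from 5.80 ± 2.02 CPM in solvent birds (n = 6) to 48.0 ± 37.5 CPM (n = 5), 8.30-fold. BBS2 reached 114 CPM in 5 mg/kg replicate 2, and its log2 fold change was 2.44 to 3.23 when 1 library was left out. SARM1, an NAD-cleaving enzyme, rose 6.19-fold, from 1.93 ± 0.569 to 12.0 ± 9.41 CPM. CHKA, choline kinase alpha of phosphatidylcholine synthesis, rose 4.61-fold, from 33.5 ± 7.68 to 154 ± 112 CPM. SBNO2, a transcriptional coregulator induced by interleukin signalling, rose 3.52-fold, from 23.0 ± 3.74 to 81.2 ± 41.1 CPM, and SLC41A1, a magnesium transporter, rose 3.13-fold, from 48.7 ± 8.14 to 152 ± 92.4 CPM.

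LOC107305801, a Z-linked gene without a symbol, named after its values were seen, rose 4.00-fold from 10.1 ± 4.43 to 40.6 ± 6.71 CPM. In edgeR's quasi-likelihood test, adjusted p was 0.0215 for BBS2 (log2 fold change 3.05, SE 0.44) and LOC107305801 (2.0, SE 0.29). It was 0.0472 for SARM1 (2.63, SE 0.43), CHKA (2.21, SE 0.37), SBNO2 (1.82, SE 0.31) and SLC41A1 (1.64, SE 0.28). For each of the 6 genes, 5 of 5 dosed birds lay above every solvent bird. The 0.5 mg/kg birds lay between the other groups in mean, at 23.4 ± 10.5 CPM for BBS2, 20.1 ± 7.91 for LOC107305801, 3.22 ± 1.30 for SARM1, 68.3 ± 17.8 for CHKA, 58.8 ± 25.3 for SBNO2 and 84.6 ± 15 for SLC41A1.

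Of 13748 genes, 1342 had an unadjusted p under 0.05, 680 higher and 662 lower, where 687.4 would be expected from evenly spread p-values. Other splits of the same birds gave a median of 919 such genes and up to 1924, and 13 of 100 splits, the real one included, reached 1342. DESeq2 called 160 genes, 95 higher and 65 lower, and limma-voom 2. DESeq2 was run on all 20308 genes with its own filter, which left 5919 without an adjusted p, and 154 of its 160 genes were among those edgeR tested. Within the numbers 1 to 3 edgeR called 0 genes and within 4 to 6 it called 1. Log2 fold changes in the 2 classes were 3.54 and 2.39 for BBS2, 1.83 and 2.21 for LOC107305801, 2.27 and 3.03 for SARM1, 2.62 and 1.22 for CHKA, 1.85 and 1.75 for SBNO2, and 1.92 and 1.14 for SLC41A1. The count of 6 became 0 without solvent replicate 3, 4, 5 or 6, 3 without solvent replicate 1, 1 without 5 mg/kg replicate 2, and 10 and 21 without 5 mg/kg replicates 3 and 4. Leaving out 1 library at a time, BBS2 passed in 7 of 11 fits, LOC107305801 in 6, and SARM1, CHKA, SBNO2 and SLC41A1 in 3 each. With a Z-linked expression covariate, or only the 2 groups in the fit, the count was 0.

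**Figure D2:**
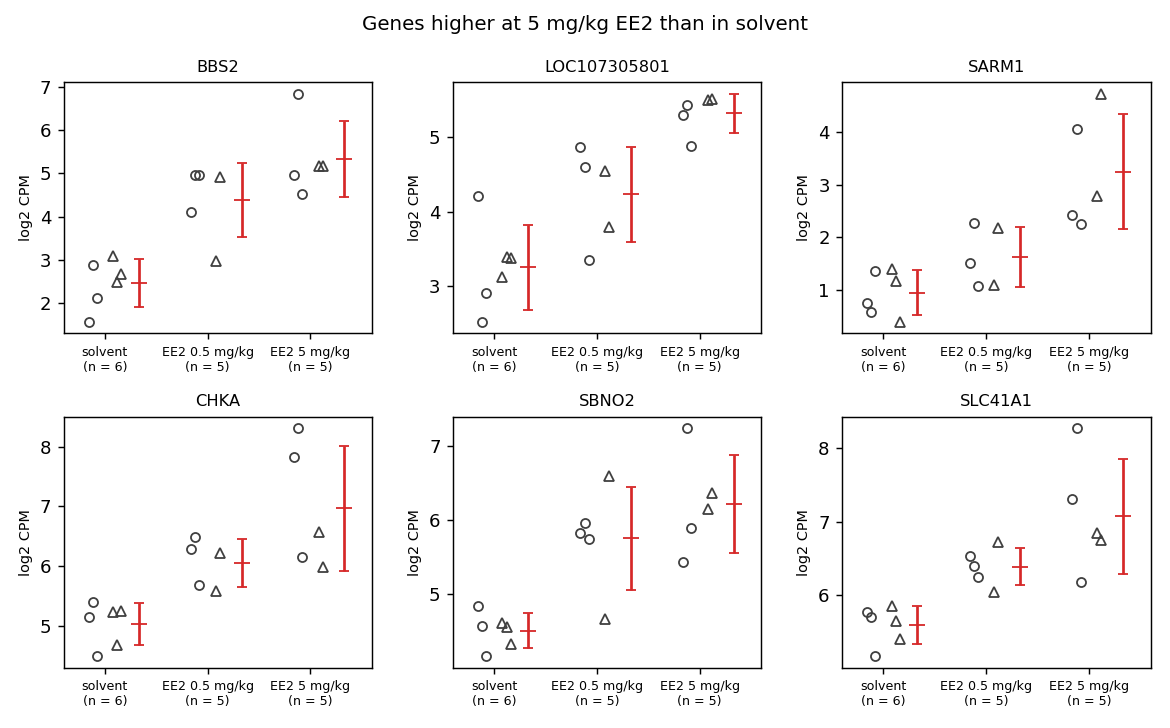
Log2 CPM (vertical axis) of the 6 genes that rose at 5 mg/kg against solvent, by group (horizontal axis). Points are birds (circles are replicates 1 to 3, triangles replicates 4 and above), and red marks are mean ± SD; all 5 birds at 5 mg/kg lie above the 6 solvent birds for each gene.

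Genes named whatever their result did not pass at 5 mg/kg. The log2 fold change was 0.35 for APOB, the protein of very low density lipoproteins and a yolk precursor, 0.13 for the estrogen receptor ESR1, -0.06 for ESR2 and -0.11 for the progesterone receptor PGR. VTG1, VTG2, VTG3 and APOV1 were not tested by name, so the yolk and estrogen list does not speak for them. The list (13 genes tested) had 9 members above 0 and 4 below and was not called, with an adjusted p of 0.986. Adjusted over the list alone, 0 of its genes rose and 2 fell, against 0 and 0 over all genes tested. These 2 were STC2, stanniocalcin 2, at -1.87 (SE 0.34; 18.8 ± 5.88 against 68.9 ± 36.8 CPM) and GREB1, an estrogen-induced coregulator in mammals, at -0.76 (SE 0.19; 1.40 ± 0.177 against 2.38 ± 0.391 CPM). Over all genes their adjusted p was 0.0692 and 0.179.

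Sterol, fatty acid, acute phase and cell cycle genes were higher as lists at 5 mg/kg (adjusted p = 0.802 for each with an estimated correlation). Cholesterol synthesis had 20 of 21 members above 0 and a median of 0.64, with MVD at 1.30 (SE 0.51), FDPS at 1.16 (SE 0.54) and SQLE at 1.14 (SE 0.52). Fatty acid and triacylglycerol synthesis had 21 of 25 above 0 and a median of 0.30, with the desaturase FADS2 at 1.20 and the malic enzyme ME1 at 1.26. Acute phase, coagulation and complement genes had 28 of 34 above 0 and a median of 0.19, with C6 at 0.89 and the fibrinogen chains FGA, FGB and FGG at 0.65, 0.67 and 0.68. The cell cycle list had 30 of 37 above 0 and a median of 0.49, with RRM1, a subunit of ribonucleotide reductase, at 1.02 and MCM6, of the replicative helicase, at 0.93. Camera gave adjusted p-values of 0.00299, 0.019, 0.0061 and 0.0061. Over all genes 0 members of these lists passed; adjusted over the list alone, RRM1 rose and 0 genes passed in the other 3 lists.

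Single birds carried part of these calls. Cholesterol synthesis scored 1.32 in 5 mg/kg replicate 3 and -1.44 in replicate 2, and its adjusted p was 0.514 without replicate 3 and 0.0579 without solvent replicate 1. For fatty acid synthesis it was 0.838, 0.0765 and 0.0929 without 5 mg/kg replicates 3, 1 and 5, and 0.0918, 0.0506 and 0.0665 without solvent replicates 1, 5 and 6. Acute phase genes gave 0.151 without solvent replicate 1 and 0.274 without 5 mg/kg replicate 2. The cell cycle scored 1.35 in 5 mg/kg replicate 1, without which its adjusted p was 0.866; it was 0.152 without 5 mg/kg replicate 5 and 0.0801 without solvent replicate 2. In the numbers 1 to 3 and then 4 to 6, the adjusted p was 0.00279 and 0.0639 for cholesterol synthesis, 0.0205 and 0.468 for fatty acid synthesis, 0.00015 and 0.782 for the acute phase, and 0.108 and 0.00151 for the cell cycle.

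Genes of the secretory pathway and the unfolded protein response were lower as a list at 5 mg/kg, with 37 of 50 members below 0 and a median of -0.18 (camera adjusted p 0.00299, and adjusted p = 0.802 with an estimated correlation). The endoplasmic reticulum chaperone HSPA5 (BiP) was at -1.58 (SE 0.43), HERPUD1 at -0.99 (SE 0.30) and PDIA3 at -0.49 (SE 0.17), with 0 members past the test over all genes and 0 adjusted over the list alone. The list was called in 11 of 11 fits that left out 1 library, with a highest adjusted p of 0.0413. Within the numbers 1 to 3 the adjusted p was 0.502, and within 4 to 6, with 3 solvent and 2 dosed birds, it was 1.87e-07. These camera values and those of the 11 fits used the preset correlation of 0.01, while the estimated correlation of the list was 0.249. They therefore do not count as repeated evidence from separate birds.

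Markers of 4 other cell types were lower as lists at 5 mg/kg (adjusted p = 0.802 for each with an estimated correlation). Endothelial genes had 16 of 18 members below 0 (median -0.23; EGFL7 -0.66, SOX18 -0.54), macrophage and Kupffer cell genes 12 of 12 (median -0.40; C1QB -0.43, TLR7 -0.67), erythroid genes 6 of 6 (median -0.53; SLC4A1, the red cell anion exchanger, -0.63) and lymphocyte genes 9 of 11 (median -0.74; LCK -1.21, CD3E -1.75). Camera's adjusted p was 0.00299, 0.0061, 0.0152 and 0.0442 in that order. 0 of their genes passed over all genes and 0 adjusted over the list alone. Solvent replicate 1 scored 1.77 for lymphocytes and 0.92 for macrophages, and without it the adjusted p was 0.808 for lymphocytes and 0.174 for macrophages.

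The endothelial call was lost without 5 mg/kg replicate 5 (adjusted p 0.282). The erythroid call was lost without solvent replicate 5 (0.0688) and without 5 mg/kg replicate 1 (0.0637), 2 (0.19) or 3 (0.0527). Lymphocytes also fell short without solvent replicate 5 (0.0805) and 5 mg/kg replicates 1 (0.252), 2 (0.127), 4 (0.178) and 5 (0.0505). In the numbers 1 to 3 and 4 to 6 the adjusted p was 0.0214 and 0.00836 for endothelium, 0.0205 and 0.0165 for macrophages, 0.0152 and 0.293 for erythroid cells, and 0.0726 and 0.504 for lymphocytes. In all, 9 of 27 lists were called, 4 higher and 5 lower, against 0 with an estimated correlation and 0 with fry. Without solvent replicate 1 the count was 5, and without the 3 libraries farthest from the rest it was 0. Scores of each called list overlapped between dosed and solvent birds, and other splits of the same birds called a median of 7 lists and up to 15. Fry's test for change in either direction called 2 lists, the yolk list (adjusted p 0.000887) and iron and calcium handling (0.00197), both of which hold STC2.

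**Figure D3:**
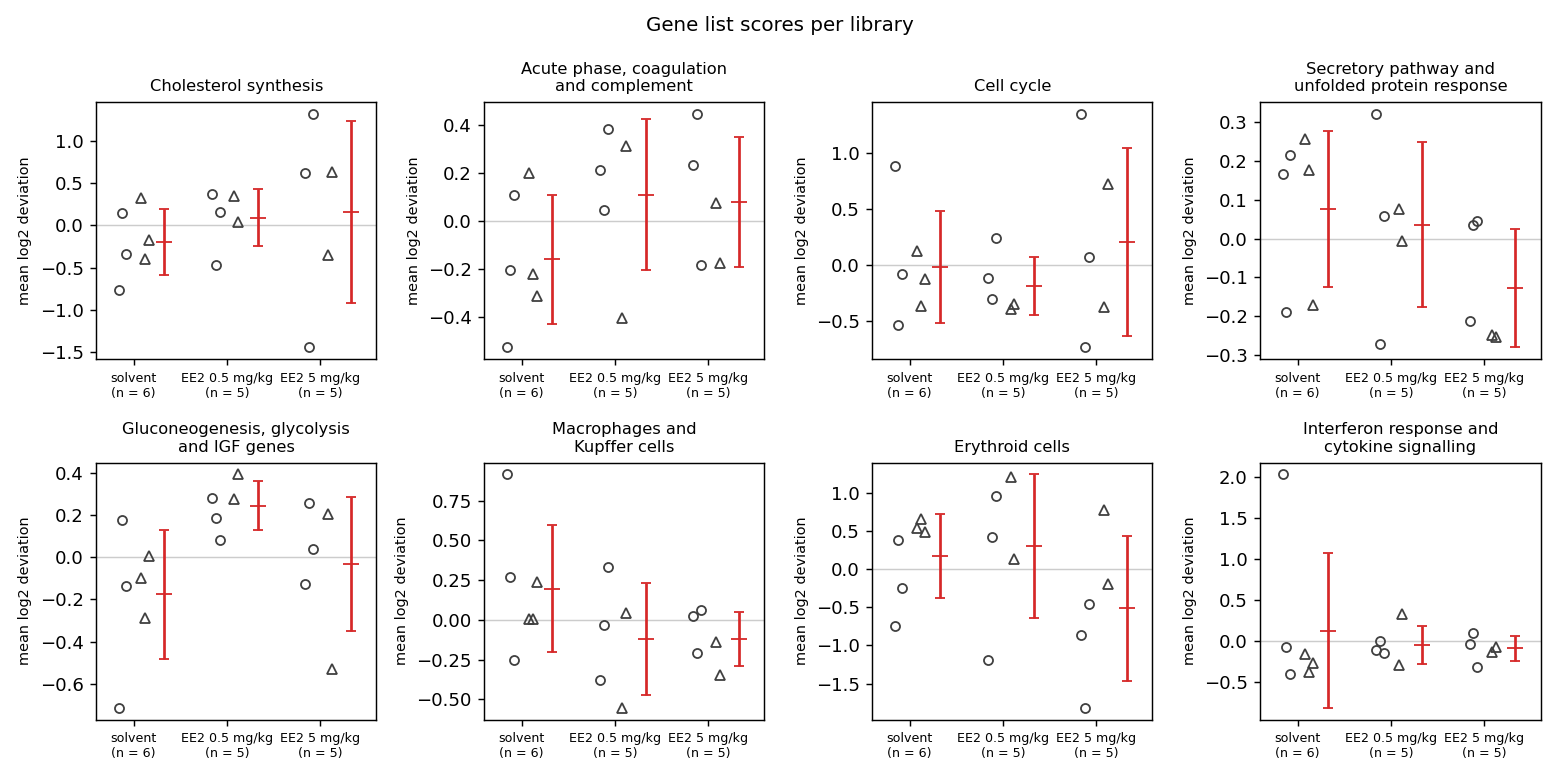
Scores of 8 gene lists, 1 per panel (mean log2 CPM deviation of their genes, vertical axis) in each library of the 3 groups (horizontal axis). Circles are replicates 1 to 3, triangles replicates 4 and above, and red marks mean ± SD; the cholesterol synthesis score lies between -1.44 and 1.32 at 5 mg/kg.

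The other 18 lists were not called at 5 mg/kg, with adjusted p-values of 0.125 to 0.986. Interferon response genes gave 0.627, with 4 members lower and 1 higher adjusted over the list alone and 0 over all genes. The lower ones were RSAD2 at -5.51, CMPK2 at -4.15, SOCS2 at -2.78 and DHX58 at -1.34, and the higher one was STAT3 at 0.80. Solvent replicate 1 alone held 1280 CPM of RSAD2 and 921 CPM of CMPK2, and scored 2.03 for the list. Adjusted over the list alone, 1 gene rose in each of 3 further uncalled lists (gluconeogenesis, bile acids and hepatocyte identity), among them the insulin receptor substrate IRS2 at 0.68 and the bile acid receptor NR1H4 at 0.76, against 0 over all genes. STC2 fell in the iron and calcium list, whose adjusted p was 0.54. Stellate cell genes gave 0.189, the circadian clock 0.269, oxidative stress 0.577, steroid hormone metabolism 0.577, the thyroid pathway 0.721, xenobiotic metabolism 0.983 and adipocytes 0.986. The sign of the median, mean and test differed for 6 uncalled lists: yolk precursors (median 0.15, mean 0.10, test lower), nuclear receptors, bile acids, xenobiotic metabolism, adipocytes and hepatocyte identity.

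The comparison of 0.5 mg/kg with solvent asked the same of the lower dose. No single gene passed the threshold, while metabolic and acute phase lists were higher and markers of macrophages, endothelium and bile duct cells were lower. With an estimated correlation 0 of the 13 list calls held, and the lowest was an adjusted p = 0.231. The lowest p-values belonged to MTMR4, SIK1, CEBPD, LMBR1L and RNF122, none past the threshold in this fit. MTMR4, a phosphoinositide phosphatase, was at 31.8 ± 2.45 CPM against 51.1 ± 5.57 in solvent birds (log2 fold change -0.69, SE 0.10, adjusted p 0.0792, 5 of 5 birds below the solvent mean). SIK1, a kinase induced by cyclic AMP, was at 119 ± 59.1 against 14.4 ± 8.53 CPM (3.05, SE 0.54, adjusted p 0.136). CEBPD, an acute phase transcription factor, was at 223 ± 45.1 against 111 ± 23.7 CPM (1.0, SE 0.18, adjusted p 0.136). LMBR1L was at -1.43 (SE 0.26, adjusted p 0.136) and RNF122 at 4.59 (SE 0.89, adjusted p 0.236). RNF122 was low in solvent birds, at 3.03 ± 2.94 against 0.122 ± 0.0570 CPM, and its log2 fold change was 3.91 to 4.87 when 1 library was left out.

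edgeR called 0 genes, with 1134 at an unadjusted p under 0.05, 527 higher and 607 lower. limma-voom called 0 and DESeq2, which left 13499 of 20308 genes without an adjusted p, called 42, 26 higher and 16 lower, all of them among the genes edgeR tested. Within the numbers 1 to 3 and 4 to 6 the count was 0 and 0. It was 1 without solvent replicate 1, 2 or 6, and 6 with only these 2 groups in the fit. ESR2, the second estrogen receptor, had a log2 fold change of 1.42 (SE 0.45), at 94.3 ± 21.2 against 35.1 ± 22.5 CPM, with an adjusted p of 0.473 and 5 of 5 birds above the solvent mean. The log2 fold change was 0.41 for ESR1, -0.53 for PGR and 0.37 for APOB.

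Acute phase, coagulation and complement genes were higher at 0.5 mg/kg in 30 of 34 members (median 0.26; adjusted p = 0.453 with an estimated correlation), with C5 at 0.53 and C6 at 0.82. Genes of gluconeogenesis, glycolysis and insulin-like growth factors were higher in 20 of 27 (median 0.23; adjusted p = 0.326 with an estimated correlation). There IGFBP1, a binding protein of insulin-like growth factors that rises on fasting, was at 2.48 (SE 0.62; 116 ± 54.3 against 20.8 ± 22.0 CPM) and IRS2 at 0.63 (SE 0.17), and both rose when adjusted over the list alone, against 0 genes over all genes tested. Camera's adjusted p was 3.84e-05 for the acute phase and 0.000641 for gluconeogenesis. Both lists were called in 11 of 11 fits that left out 1 library. In the numbers 1 to 3 and 4 to 6 the adjusted p was 8.79e-07 and 0.257 for the acute phase and 0.0168 and 0.000596 for gluconeogenesis.

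Lists of lipid and bile acid metabolism and of hepatocyte factors were also higher at 0.5 mg/kg, with adjusted p = 0.231 to 0.685 with an estimated correlation. Bile acid genes were above 0 in 12 of 15 (median 0.27; NR1H4 0.61, the bile salt export pump ABCB11 0.37), lipoprotein genes in 15 of 22 (median 0.23; NPC1 0.60, LPL 1.15), fatty acid oxidation in 22 of 27 (median 0.14; PPARA 0.50, PDK4 1.68, PPARGC1A 1.53) and cholesterol synthesis in 17 of 21 (median 0.20; HMGCS1 1.09, INSIG1 0.88). Hepatocyte identity genes were above 0 in 15 of 19 (median 0.24), although CEBPA was at -1.0. NPC1, a lysosomal cholesterol transporter, rose when adjusted over the list alone, and 0 genes of these 5 lists passed over all genes. Camera's adjusted p was 0.00858 for bile acids (adjusted p = 0.231 with an estimated correlation), 0.00926 for lipoproteins and 0.00817 for hepatocyte identity (adjusted p = 0.449 for both with an estimated correlation). It was 0.0128 for fatty acid oxidation and 0.0168 for cholesterol synthesis (adjusted p = 0.648 and 0.685 with an estimated correlation).

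Nuclear receptor, yolk and ribosome biogenesis genes were also higher as lists at 0.5 mg/kg (adjusted p = 0.326, 0.326 and 0.449 with an estimated correlation). The nuclear receptors had 18 of 30 above 0 (median 0.06), the yolk and estrogen list 9 of 13 (median 0.31; the transferrin gene TF 0.93, LPL 1.15) and ribosome biogenesis 22 of 31 (median 0.09). MYC was at 1.70 (SE 0.40) and rose adjusted over the list alone, as did 0 genes of the other 2 lists, against 0 over all genes. The camera test gave adjusted p-values of 0.0168, 0.0292 and 0.0442. For ribosome biogenesis it was 0.0519 with the 2 classes of numbers as a covariate.

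Each of these 8 lists lost its call without some library at 0.5 mg/kg. Without solvent replicate 1 the adjusted p was 0.055 for hepatocyte identity and for nuclear receptors, 0.284 for fatty acid oxidation, 0.205 for cholesterol synthesis, 0.107 for the yolk list and 0.0505 for ribosome biogenesis. Without 0.5 mg/kg replicate 5 it was 0.0535 for hepatocyte identity, 0.0524 for bile acids, lipoproteins and nuclear receptors, and 0.078 for the yolk list. Without replicate 4 it was 0.058 for fatty acid oxidation, 0.0936 for cholesterol synthesis and 0.122 for ribosome biogenesis. Without replicate 1 it was 0.0788 for cholesterol synthesis, 0.0554 for nuclear receptors, 0.0722 for the yolk list and 0.31 for ribosome biogenesis. Lipoproteins gave 0.0511 without solvent replicate 6, the yolk list 0.0599 without solvent replicate 5, and ribosome biogenesis 0.112, 0.166 and 0.0691 without solvent replicates 2, 3 and 4 and 0.0543 without 0.5 mg/kg replicate 2.

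In the numbers 1 to 3 and then 4 to 6, the adjusted p at 0.5 mg/kg was 0.0864 and 0.00246 for bile acids, 0.883 and 1.2e-05 for lipoproteins, 0.0612 and 0.00674 for fatty acid oxidation, and 0.0612 and 0.0106 for cholesterol synthesis. It was 0.0188 and 0.0451 for hepatocyte identity, 0.0369 and 0.159 for nuclear receptors, 0.216 and 0.00707 for the yolk list, and 0.0414 and 0.396 for ribosome biogenesis.

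Macrophage genes were lower at 0.5 mg/kg in 11 of 12 members (median -0.29; C1QB -0.54, CTSS -0.87), endothelial genes in 16 of 18 (median -0.22; LYVE1 -0.79) and cholangiocyte genes in 9 of 9 (median -0.48). The camera test gave adjusted p-values of 0.00449, 0.0173 and 0.0173, with an adjusted p = 0.453, 0.648 and 0.449 with an estimated correlation. Adjusted over the list alone, 1 cholangiocyte gene fell and 0 genes of the macrophage and endothelial lists passed, and over all genes 0 genes of the 3 lists passed. Solvent replicate 1 scored 0.92 for macrophages and 0.87 for cholangiocytes, and without it the adjusted p was 0.0726 for macrophages, 0.0505 for endothelium and 0.147 for cholangiocytes. Without 0.5 mg/kg replicate 4 it was 0.0791, 0.1 and 0.058, and for endothelium also 0.128 without solvent replicate 3 and 0.0602 without 0.5 mg/kg replicate 2. In the numbers 1 to 3 and 4 to 6 it was 0.0188 and 0.00707 for macrophages, 0.0369 and 0.109 for endothelium, and 0.0977 and 0.0382 for cholangiocytes.

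In all, 13 of 27 lists were called at 0.5 mg/kg, 10 higher and 3 lower, against 0 with an estimated correlation and 0 with fry. The count was 5 without solvent replicate 1, and 7 and 8 without 0.5 mg/kg replicates 4 and 5. Other splits of the same birds called a median of 7 lists and up to 18. Scores of the called lists overlapped between dosed and solvent birds except for the yolk list, with 0.16 ± 0.12 in 5 dosed birds against -0.12 ± 0.12 in 6 solvent birds. The 14 uncalled lists had adjusted p-values of 0.195 to 0.804. Among these, the circadian clock (0.536) had 2 genes that rose adjusted over the list alone and 0 over all genes, NFIL3 at 0.88 and CRY1 at 0.50. The sign of the median, mean and test differed for 5 uncalled lists, xenobiotic metabolism, the thyroid pathway, iron and calcium, the circadian clock and adipocytes.

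The comparison of 5 with 0.5 mg/kg asked whether the doses differed. No single gene passed. Cell cycle genes were higher as a list at 5 mg/kg and erythroid, secretory pathway and bile acid genes lower, with adjusted p = 0.663, 0.635, 0.663 and 0.283 with an estimated correlation. The 5 genes with the lowest p, each with an adjusted p of 0.265, were LOC107321556 at 2.74 (SE 0.47), TIMP3, an inhibitor of matrix metalloproteinases, at -0.80 (SE 0.15; 82.9 ± 14.5 against 145 ± 31.3 CPM), MCL1, an anti-apoptotic protein, at -0.79 (SE 0.15; 112 ± 10.4 against 193 ± 39.1 CPM), LOC107307680 at -1.66 (SE 0.32) and the nucleoporin NUP93 at 0.81 (SE 0.16; 9.12 ± 1.88 against 5.20 ± 0.681 CPM). edgeR called 0 genes, with 997 at an unadjusted p under 0.05, 540 higher and 457 lower, limma-voom 0 and DESeq2 26, 12 higher and 14 lower, of which 23 were among the genes edgeR tested. DESeq2 left 1572 genes without an adjusted p. Within the numbers 1 to 3 and 4 to 6 the count was 0 and 0, and it was 2 without 5 mg/kg replicate 4. The log2 fold change was -1.49 for ESR2 (adjusted p 0.55), -0.28 for ESR1, 0.42 for PGR and -0.02 for APOB.

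The cell cycle list was higher at 5 than at 0.5 mg/kg in 34 of 37 members (median 0.43; adjusted p = 0.663 with an estimated correlation), with RRM1 at 0.93 (SE 0.24) and TYMS, thymidylate synthase, at 1.53; adjusted over the list alone RRM1 rose, against 0 genes over all genes. Erythroid genes were lower in 6 of 6 (median -0.89; RHAG -0.96), the secretory pathway in 39 of 50 (median -0.15; PDIA6 -0.49) and bile acid genes in 11 of 15 (median -0.21; SLC51B -0.47, KLB -0.51), and 0 genes of these 3 lists passed over all genes or adjusted over the list alone. With camera, adjusted p was 0.00158, 0.00171, 0.00207 and 0.0143, and for the last 3 lists adjusted p = 0.635, 0.663 and 0.283 with an estimated correlation. In the yolk list and in the iron and calcium list, both uncalled at 0.0596 and 0.253, STC2 (-1.63, SE 0.35) fell adjusted over the list alone.

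The cell cycle call was lost without 5 mg/kg replicate 1 (adjusted p 0.406), while the erythroid call held in 10 of 10 fits that left out 1 library. The secretory call was lost without 0.5 mg/kg replicate 1 (0.177) and 5 mg/kg replicate 4 (0.0983), and the bile acid call without 0.5 mg/kg replicates 1 (0.0515) and 5 (0.145) and 5 mg/kg replicate 4 (0.0711). In the numbers 1 to 3 and 4 to 6 the adjusted p was 0.0532 and 0.000586 for the cell cycle, 0.000121 and 0.0745 for erythroid cells, 0.496 and 2.95e-05 for the secretory pathway, and 0.454 and 0.00122 for bile acids. In all, 4 of 27 lists were called, against 0 with an estimated correlation and 0 with fry. The count was 2 without 0.5 mg/kg replicate 1, 13 and 10 without 0.5 mg/kg replicates 3 and 4, and 15 without 5 mg/kg replicate 2. Without the 3 libraries farthest from the rest it was 1. Other splits of the same birds called a median of 6 lists, more than the real 4, and up to 19. The other 23 lists had adjusted p-values of 0.0596 to 0.998. The sign of the median, mean and test differed for 8 uncalled lists, fatty acid oxidation, steroid hormone metabolism, the thyroid pathway, interferon response, gluconeogenesis, oxidative stress, macrophages and adipocytes.

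The responses to the 2 doses were compared across genes, which are not independent replicates. The log2 fold changes of 5 and 0.5 mg/kg against the same solvent birds correlated with r = 0.531 and had the same sign in 67.8% of genes. In 10 simulations all libraries, solvent ones included, were drawn without an effect, each gene on its own, with the real means, depths and spread. They gave a mean r of 0.440 (SD 0.0172) and 64.7%. The real solvent birds were not used in them, so these values do not show what sharing those birds would give. The covariance was 0.119 against 0.0589 in the simulations, a difference of 0.0596. From differences of mean log2 CPM, r was 0.530 and the covariance 0.0853 with all solvent birds. On that scale, with the solvent birds split into separate sets of 3 for the 2 doses, the mean r was 0.144 (0.0872 to 0.215 over 20 splits) and the mean covariance 0.0304. At an unadjusted p under 0.05, 152 genes were higher and 204 lower at both doses. The simulated unchanged groups, which share simulated solvent birds and hold no effect, gave means of 70.7 and 50.6 (up to 82 and 63). Their lists were shorter, with means of 313.7 and 320.2 genes higher and 329.9 and 340.2 lower, against 680 and 527 higher and 662 and 607 lower in the data, so these counts of shared genes cannot be compared directly. Independent lists would share 26.1 and 29.2 genes at the observed lengths and 7.31 and 8.19 at the simulated ones.

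BBS2 stood in a run of 4 neighbours on chromosome 11 that were higher at 5 mg/kg than in solvent birds, a run chosen after its values were seen. OGFOD1 was at 0.74 (SE 0.17, adjusted p 0.126; 9.00 ± 2.53 against 5.38 ± 0.848 CPM), BBS2 at 3.05, LOC107319226 at 3.75 (SE 1.03, adjusted p 0.216; 102 ± 132 against 7.61 ± 11.1 CPM) and NUP93 at 0.80 (SE 0.15, adjusted p 0.0848; 9.12 ± 1.88 against 5.25 ± 0.500 CPM). BBS2 passed the threshold and the other 3 did not. The flanking genes NUDT21, TMEM170A and CFDP1 were at 0.09, 0.11 and 0.04. At 0.5 mg/kg against solvent the 4 genes were at 0.26, 2.01, 2.47 and -0.02.

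**Figure D4:**
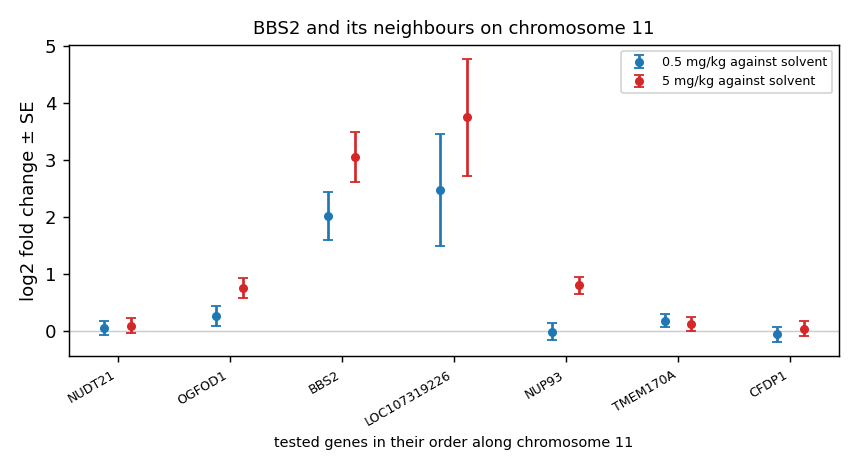
Log2 fold changes (vertical axis, error bars SE) of OGFOD1, BBS2, LOC107319226, NUP93 and the flanking genes NUDT21, TMEM170A and CFDP1 in chromosome order (horizontal axis) for both doses against solvent. At 5 mg/kg the 4 genes lie between 0.74 and 3.75 and the flanking genes between 0.04 and 0.11.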

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

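The tests of the run on chromosome 11 were chosen after its values were seen, and so were the comparisons of unadjusted counts between splits and of balanced splits, while the comparisons with other splits of the libraries were planned.

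For 5 mg/kg against solvent, 1 of 100 splits of the 11 libraries, the real one, called as many genes as the 6 observed. The highest count of another split was 5, so the count of 6 stood apart at the share of 0.05, by a narrow margin. It was 1 of several counts compared without correction, and it ran from 0 to 21 when 1 library was left out. Chance is therefore not firmly excluded for it. For 0.5 mg/kg against solvent and for 5 against 0.5 mg/kg the real count was 0 by edgeR, with highest other counts of 1 and 2. A count of 0 is reached by all 100 of 100 splits whatever the data, so these splits say nothing about chance. DESeq2 called 42 and 26 genes there. Genes at an unadjusted p under 0.05 numbered 1134 at 0.5 mg/kg against solvent, reached by 1 of 100 splits, the real one (highest other 1133, median 632). They numbered 997 between the doses, reached by 16 (highest other 1313, median 679), and 1342 at 5 mg/kg against solvent, reached by 13 (highest other 1924, median 919). At a share of 0.05, the unadjusted count at 0.5 mg/kg stood apart from the other splits, by 1 gene, and the other 2 counts did not. Since these counts were chosen after their values were seen, chance is not excluded for any of them. The counts of gene lists were reached by 31 of 100 splits at 5 mg/kg (9 lists, highest other 15), by 11 at 0.5 mg/kg (13 lists, highest other 18) and by 85 between the doses (4 lists, highest other 19), so chance cannot be excluded for any of these 3 counts. Many splits, unlike the real one, were not balanced over the numbers 1 to 3 and 4 to 6, so differences between these classes enter their counts. Among the balanced splits, the real one included, the count of 6 genes was reached by 1 of 47. The unadjusted counts were reached by 5 of 47 at 5 mg/kg (highest other 1924), 1 of 47 at 0.5 mg/kg (highest other 1050) and 9 of 45 between the doses (highest other 1281). The counts of lists were reached by 14, 8 and 40 in that order (highest other 14, 18 and 19), so each of these 7 counts stood on the same side of the share of 0.05 as among all splits.

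Among 156 groups of values examined, 7 held a library far from the others of its group, where chance alone gives about 1 in 20, or 7.8. BBS2 stood at 6.84 log2 CPM in 5 mg/kg replicate 2, with the nearest bird at 5.17, and NUP93 at 2.56 in 5 mg/kg replicate 4, with the nearest at 3.24. Solvent replicate 1 had scores of -0.62 for fatty acid oxidation (nearest -0.07), 2.03 for interferon response (nearest -0.08) and 1.77 for lymphocytes (nearest 0.15). The adipocyte score was 0.80 in 5 mg/kg replicate 2 (nearest -0.18). Genes without a match in the name table took 3.21% of counts in 5 mg/kg replicate 5, with the nearest bird at 0.753%.

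BBS2 is 1 of 4 neighbours on chromosome 11, with OGFOD1, LOC107319226 and NUP93, that were higher at 5 mg/kg at an unadjusted p under 0.01. In 1000 shuffles of the order of 12652 genes, of which 214 were higher at that level, 1 shuffle held as long a run, which argues against a chance order. Reads that run on from these genes into NUP93 would make their deviations from the group means move together. Over all birds the highest correlation of NUP93 with the other 3 was r = 0.104 (rho = 0.103, permutation p 0.71 and 0.706, n = 16). This argues against a strong link of that kind for NUP93, while 16 birds are too few to exclude a weaker one. In the numbers 4 to 6 r was 0.234 with OGFOD1, 0.322 with BBS2 and 0.324 with LOC107319226, against -0.213, -0.350 and -0.0503 in 1 to 3. Among OGFOD1, BBS2 and LOC107319226 the lowest was r = 0.593 (rho = 0.632, permutation p 0.0155 and 0.0104, adjusted 0.031 and 0.0208 over 6 pairs), so shared reads or transcripts may link these 3, and a response of each gene to the dose cannot be told apart from that without reads. This lowest pair, OGFOD1 with LOC107319226, gave r = 0.393 without the 2 farthest birds, and 0.735 and 0.2 in the numbers 1 to 3 and 4 to 6.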

How the results depend on the processing

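Leaving out the 3 libraries farthest from the rest, the restrictions to replicates 1 to 3 or 4 to 6, the covariate for these 2 classes and the block by the number in brackets were chosen after the data were seen; the other alternatives were planned. The cause of a moved value was not tested, except that fits of 2 groups or fewer libraries have fewer birds to estimate the spread.

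For 5 mg/kg against solvent, the 6 genes were all called again with DESeq2 size factors, no filter, a mean of at least 1 CPM, robust dispersions, a log2 fold change of at least 1 and the DESeq2 test, which called 160. The count was 0 with only the 2 groups, 0 with the Z-linked covariate, 0 with replicates 1 to 3, 1 with replicates 4 to 6, 3 with a surrogate variable, 3 with the class covariate, 2 with limma-voom and 2 without the 3 libraries farthest from the rest. Leaving out 1 library gave 0 to 21. For 0.5 mg/kg against solvent the 0 of edgeR (1134 unadjusted) became 1 with a mean of at least 1 CPM, 6 with only the 2 groups, 1 with a surrogate variable, 1 without the 3 libraries, 42 with DESeq2, and 0 to 1 without 1 library. For 5 against 0.5 mg/kg the 0 of edgeR (997 unadjusted) became 26 with DESeq2 and 0 to 2 without 1 library. Adjusted p ranged over the alternatives from 4.8e-09 to 0.78 for BBS2, 1.34e-07 to 0.565 for LOC107305801, 1.91e-06 to 0.738 for SARM1, 5.65e-06 to 0.784 for CHKA, 1.85e-05 to 0.784 for SBNO2 and 2.9e-05 to 0.784 for SLC41A1, and the log2 fold change of each stayed above 0. At 0.5 mg/kg against solvent it ran from 8.61e-07 to 0.915 for MTMR4, 3.1e-06 to 0.928 for SIK1 and 0.000176 to 0.915 for CEBPD. LMBR1L ran from 0.0278 to 0.915 and RNF122 from 0.0836 to 0.877. Between the doses the lowest was 0.000158 for LOC107321556, 0.00121 for TIMP3 and LOC107307680, 0.00178 for MCL1 and 0.00287 for NUP93.

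Called lists numbered 9, 13 and 4 in the 3 comparisons, and 0 in each with an estimated correlation or fry. Without the 3 libraries there were 0, 9 and 1, with replicates 1 to 3 there were 9, 8 and 2, and with replicates 4 to 6 there were 5, 12 and 13. Leaving out 1 library gave 5 to 10, 5 to 15 and 2 to 15. The correlation of the doses was 0.144 with split solvent birds.

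The direction of some genes that did not pass also turned. APOB between the doses was at 0.14 in replicates 1 to 3 and at -0.20 to 0.12 without 1 library. ESR1 at 5 mg/kg was at -0.0295 with a surrogate variable and at -0.13 to 0.33 without 1 library. ESR2 at 5 mg/kg was at 0.15 without the 3 libraries, 0.35 in replicates 4 to 6 and -0.47 to 0.25 without 1 library. PGR was at -0.13 between the doses in replicates 1 to 3, and at 5 mg/kg at 0.37 in replicates 4 to 6 and -0.433 to 0.0275 without 1 library.

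Libraries of different groups with the same replicate number did not deviate together: 2 of 15 pairs had r above 0.1 (median 0.0237, range -0.0842 to 0.203; other pairs median 0.00214), and 5 of 15 libraries correlated best with their own number. With the number as a replicate block, 2 genes were called at 5 mg/kg against solvent (1 of the 6, and 1 lower), 0 and 0 in the other comparisons, and 6, 12 and 4 lists, and ESR2 at 5 mg/kg stood at 0.14. The number in brackets in the labels differs for 5 mg/kg replicates 4 and 5. By that number 1 of 14 pairs had r above 0.1 (median 0.0232) and 3 of 16 libraries correlated best with their own number, and as a replicate block it left 1, 0 and 0 genes and 8, 12 and 4 lists. At these depths and this spread, 2-fold changes were recovered in 38% to 49% of simulated genes and 4-fold changes in 80% to 87%, so 2-fold changes can be missed.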

Other observations

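The tests of the genes high in 5 mg/kg replicate 1, of Z-linked expression and of feeding state were all chosen after the values were seen, except that a Z-linked covariate was planned.

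In single birds, some genes reached levels far above all other libraries. Solvent replicate 1 held 77 genes at least 2 log2 units above every other library, among them RSAD2 at 1280 CPM, CMPK2 at 921 CPM and DDX60 at 809 CPM, all induced by interferon. In 0.5 mg/kg replicate 3, 6 genes did so, with LOC107321681 at 9885 CPM and MATN4, a cartilage matrix protein, at 2711 CPM. In 5 mg/kg replicate 5, 8 genes did, the highest a gene without a match in the name table at 22335 CPM. ACOT9 was at 3951 CPM there, TTC7B at 1354 CPM and MBOAT1 at 617 CPM. The other libraries held 0 to 3 such genes, apart from 5 mg/kg replicate 1 with 15.

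In 5 mg/kg replicate 1, 7 genes lay at least 3 log2 units above every other library, 6 without a symbol and TCN2, a vitamin B12 carrier, at 304 CPM. LOC107317565 on chromosome 8 reached 7415 CPM and LOC107319873 on chromosome 1 reached 6678 CPM, against 0.554 ± 0.470 and 1.51 ± 0.722 CPM in 6 solvent birds. LOC107317352, at 527 CPM, neighbours LOC107317565 between SSX2IP and CTBS. RNA of the cell types of 7 tested lists was argued against, since their highest score in that bird was 0.0865 on the log2 scale, and other tissues were not tested. A response to the dose stays open: 2 of the 7 genes were higher in the other 9 dosed birds than in solvent birds in an exact permutation test, two-sided. LOC107317565 was at 1.85 ± 1.23 against -1.03 ± 1.12 log2 CPM (exact p 0.0002, adjusted 0.0014 over 7 genes), with 9 of 9 dosed birds above every solvent bird. LOC107319873 was at 2.04 ± 0.72 against 0.53 ± 0.66 (exact p 0.0004, adjusted 0.0014), with 8 of 9. Within the numbers 1 to 3 and 4 to 6 the exact p was 0.0357 and 0.0286 for LOC107317565 and 0.0179 and 0.0286 for LOC107319873, where 0.0179 and 0.0286 are the smallest possible. The adjusted p of the other 5 genes was 0.0874, 0.0874, 0.46, 0.755 and 0.755. It is a hypothesis that these 2 genes are estrogen-induced. This bird was the highest of its group for 0 of the 6 genes called at 5 mg/kg, and edgeR's adjusted p at 5 mg/kg was 0.0848 for LOC107317565 and 0.102 for LOC107319873.

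The split of Z-linked expression by library number may reflect the sex of the birds, which the labels do not give and which the checks below do not decide. Between the 7 libraries numbered 4 to 6 and the 9 numbered 1 to 3, with treatment in the fit, edgeR called 171 genes. Of these 153 lie on Z and 152 of them were lower in 4 to 6, which is 25% of 613 Z-linked genes against 0.137% of 13135 others. A library batch acting on genes of every chromosome is argued against, since the ratio of these shares is 182. The median difference was -0.46 for Z-linked genes (quartiles -0.75 and -0.21) and 0.01 for other genes. These are the Z-linked genes in which the split was first seen, and scaling sets other genes near 0, so the values do not test the number of Z copies. Genes of the W chromosome, which only females carry, were not analysed here by name (0 of 17 listed genes matched). In a search without names, 0 genes lay at least 8-fold higher in every library numbered 4 to 6 than in all numbered 1 to 3 (taken as at least 0.05 CPM). Whether the transcriptome used held W genes is not known, so this empty search does not weigh against sex, which stays open. Genes elsewhere included LOC107325623 on chromosome 28 at 1.20 (adjusted p 9.08e-07). A difference of the dose effect between the 2 classes was called in 0 genes by edgeR at either dose, with 570 at 5 mg/kg and 415 at 0.5 mg/kg at an unadjusted p under 0.05.

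Some genes of fed and fasted metabolism, chosen after their values were seen, varied more among solvent birds than at 0.5 mg/kg, a difference that was not tested. The SD of log2 CPM was 2.86 in solvent birds against 0.384 at 0.5 mg/kg for G0S2, and 0.898 against 0.366 for PDK4. G0S2, an inhibitor of fat breakdown, lay between 2.30 and 8.54 log2 CPM in solvent birds, 0.89 and 1.82 at 0.5 mg/kg, and 0.71 and 7.34 at 5 mg/kg. At 0.5 mg/kg it was at -5.85 against solvent (adjusted p 0.379, 5 of 5 birds below every solvent bird). The glycogen-targeting subunits PPP1R3B and PPP1R3C were at -3.00 and -2.80 (adjusted p 0.325 for both, 5 of 5). A candidate explanation is that feeding state differed between birds within groups. If so, PCK1, IGFBP1, PDK4 and PPARGC1A should fall as G0S2 rises with treatment in the fit, and 2 of the 4 did: IGFBP1 with a slope of -0.40 (adjusted p 0.0179) and PPARGC1A with -0.41 (0.0179), while PDK4 at -0.36 (0.0973) and PCK1 at -0.89 (0.211) did not pass. In that fit 12 other genes followed G0S2, 9 upward and 3 downward, among them ANGPTL4 with a slope of 0.76 (adjusted p 4.77e-05), PPP1R3C with 0.40 and MYC with -0.25. ZFP36L1, with a slope of 0.14 (adjusted p 0.0449), had an adjusted p of 0.0557 with the class of numbers in the fit. With G0S2 in the fit, genes at an unadjusted p under 0.05 numbered 743 in place of 1134 at 0.5 mg/kg, 1386 in place of 1342 at 5 mg/kg and 675 in place of 997 between the doses. Feeding state and an effect of the lower dose on these genes cannot be told apart here.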
